A study of Mus musculus with 14 samples.

How the data were processed

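RNA from 14 samples of dissociated mouse cerebellum was measured, 1 expression array per sample. Per the labels, the mice were heterozygous for patched (Ptch1, the receptor that holds hedgehog signalling in check). They give 3 groups. The first is granule cell precursors (GCP, n = 4), the dividing cells that make cerebellar granule neurons, from mice aged 7 days. The second is preneoplastic cells, called pretumor (n = 5), from mice aged 6 weeks. The third is tumor cells (n = 5) from mice aged 10 to 25 weeks that showed signs of medulloblastoma, a cerebellar tumor. Per the labels' protocols, tissue was digested with papain and DNase, the suspension was spun on a Percoll gradient, the cells at the border of the 35% and 65% steps were kept and frozen, and these cells were not sorted by flow cytometry. Age and stage differ together between the groups, so no comparison parts one from the other. The titles number the samples within a group, and nothing says that these samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

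The deposited table holds 1 intensity per probe set and array on a linear scale, for 12488 probe sets. The method by which the authors summarised and normalised these intensities is not given in the sources used here. The medians of the 14 arrays lay within 0.094 log2 units of each other, below the limit of 0.2 fixed beforehand, so the table was taken as already normalised and no further normalisation was applied. Of all values, 70.5% lay below 16, in a narrow band near the lowest intensities that is called the low band here. The limit of 16 was chosen after seeing the data. For arrays there is no read depth; the number of arrays limits the precision. The low band is taken to lie close to background, which was not measured here.

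The 66 control probe sets were set aside, which left 12422. Values were floored at the 10th percentile of all values, 2.46, and taken to log2. At this floor 404 probe sets had the same value on all 14 arrays; they were kept and could not be called. A linear model with 3 group means was fitted to each probe set with limma 3.58.1 in R 4.3.3, with 11 residual degrees of freedom and empirical Bayes moderation (0.83 prior degrees of freedom). The 3 contrasts were pretumor minus GCP, tumor minus GCP and tumor minus pretumor. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 12422 probe sets, and a probe set was called at an adjusted p under 0.05. A probe set apart from both was called in pretumor minus GCP and in tumor minus pretumor, with pretumor higher than both other groups or lower than both. A shared change was called against GCP in pretumor and in tumor in the same direction. Error is given as SD, and n is 4 for GCP and 5 for each other group.

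Gene symbols came from the array's probe annotation and were checked by name alone against a reference gene table of the assembly GRCm38.p6. Of the 12422 probe sets, 10833 had 1 symbol, 396 had several and 1193 had none. The reference table held 10817 of the single symbols, and 0 symbols needed an update. The 8251 genes were each represented by the probe set with the highest mean over all arrays, and in 0 genes were probe sets called in opposite directions within a contrast. Where 1 group mean lay below 16, a fold is given against 16 as a lower bound ("at least"), and where both lay below 16 no fold is given. The group means behind the folds of Ptgds, Smpdl3a, Gdf10, Lyz2, Slc8a1, Gsn and Myc include arrays in the low band, 3 of the 5 tumor arrays for Myc, so these folds are less certain.

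Genes to be named were fixed by a rule before the data were examined. The rule took Ptch1 with each of its probe sets. For each contrast it took the 8 single-symbol genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap. It took the genes furthest apart from both, up to 8 in each direction. For each gene list it took up to 3 called members with the largest change, or the member with the highest mean where none was called. A gene named by any part could be quoted in every contrast. Other genes are named where stated as chosen after their values were seen.

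Before the data were examined 30 gene lists were fixed. They cover the hedgehog pathway, granule cell precursor identity, G1/S and DNA replication, mitosis, cell cycle inhibitors, apoptosis regulators, migration and axon guidance, postmitotic granule neurons, synapse and neurofilament, chromatin and DNA methylation, neural stem and progenitor genes, growth factor signalling through IGF and its relatives, the Wnt and BMP pathway, immediate early and stress genes, glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, and MHC and interferon response. The rest are markers of other cell types that the suspension could hold: Purkinje cells, inhibitory interneurons, astrocytes and Bergmann glia, oligodendrocytes and their progenitors, microglia and macrophages, lymphocytes, endothelium and pericytes, red blood cells, meninges and extracellular matrix, and choroid plexus and ependyma. Each list was tested in each contrast with camera in limma, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 30 lists of a contrast. Member counts are given over all probe sets and adjusted over the list alone. The same test with an estimated correlation and limma's fry, which asks whether a list moves on balance one way without comparing it with other genes, were run as alternatives.

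The fit was tested on simulated data for 12422 probe sets with 200 planted changes per contrast among probe sets above the low band. Of 100 planted changes of 1 log2 unit, it recovered 64 in pretumor against GCP, 63 in tumor against GCP and 70 in tumor against pretumor; of 100 planted changes of 2 log2 units it recovered 97, 96 and 98. False calls numbered 13, 19 and 13. A change of 0.5 log2 units planted in the 36 measured genes of the G1/S list in tumor against GCP gave camera an adjusted p of 1.25e-35, with 0 other lists called. The simulated genes were independent of each other, while the real genes of this list had an estimated correlation of 0.186. The simulation therefore does not show how often camera calls lists falsely in the real data.

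Comparisons that share a group share its chance values. Unchanged groups were therefore simulated 20 times on the real group sizes, expected overlaps of independent calls were computed, and the shared group was split. The simulation drew every value independently, while real arrays can deviate together, so its ranges may be too narrow. Each count of calls was compared with up to 100 splits of the same samples into groups of the same sizes. Single values were compared with two-sided exact permutation tests, and correlations across arrays with 100000 permutations within groups. Alternatives fixed before the data were examined were quantile normalisation, median-centred arrays, a floor at the 25th percentile, a pseudocount of 16 without floor, removal of dim probe sets below the 30th percentile of mean level, the compared groups fitted alone, the replicate number as a block, trend and robust moderation, array weights, the mean over a gene's probe sets, each array left out in turn, a 2-fold minimum, and an adjusted p under 0.01. Alternatives added after seeing the data were a floor at 16, a covariate for an axis of deviations that crosses the groups, the arrays on either side of that axis alone, the removal of pretumor 3, tumor 2 and tumor 3, and the use of probe sets with a plain suffix alone. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.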

Results

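Gene expression in cerebellar cells of patched heterozygous mice was measured at 3 stages on 14 arrays. The earliest stage was granule cell precursors of 7-day-old mice (GCP, n = 4). The later stages were preneoplastic cells of 6-week-old mice (pretumor, n = 5) and tumor cells of mice aged 10 to 25 weeks (tumor, n = 5). The median intensity per array ran from 4.12 to 4.39, and between 29.2% and 29.8% of probe sets reached an intensity of 16. The mean correlation of an array with the rest of its group ran from 0.985 to 0.996. The first principal component, 28.7% of the variance, placed the GCP arrays between -29.0 and -24.3, the pretumor arrays between 0.93 and 5.28 and the tumor arrays between 14.7 and 24.4. The second component, 20.2% of the variance, crossed all 3 groups. An axis fitted to the deviations from the group means took 35.4% of their variance, with pretumor 3 at 28.4 and tumor 2 at 29.8 furthest from the other arrays. The GCP arrays formed 2 pairs, GCP 1 with GCP 2 (r = 0.9977) and GCP 3 with GCP 4 (r = 0.9975), against r of 0.9939 to 0.9956 across these pairs. On this axis GCP 1 and GCP 2 lay at -13.8 and -8.15, and GCP 3 and GCP 4 at 12.2 and 9.78. The 4 GCP arrays may therefore not be 4 independent replicates. The log2 ratio of 3' to 5' signal of Gapdh was 0.46 and 0.56 in GCP 1 and GCP 2, and -0.018 in both GCP 3 and GCP 4. The actin ratio did not part these pairs and ran from 3.93 to 4.87 over all arrays. The cause of the pairs was not tested, and both ratios are set against the axis further below. Levels below are group means of log2 intensity ± SD.

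**Figure D1:**
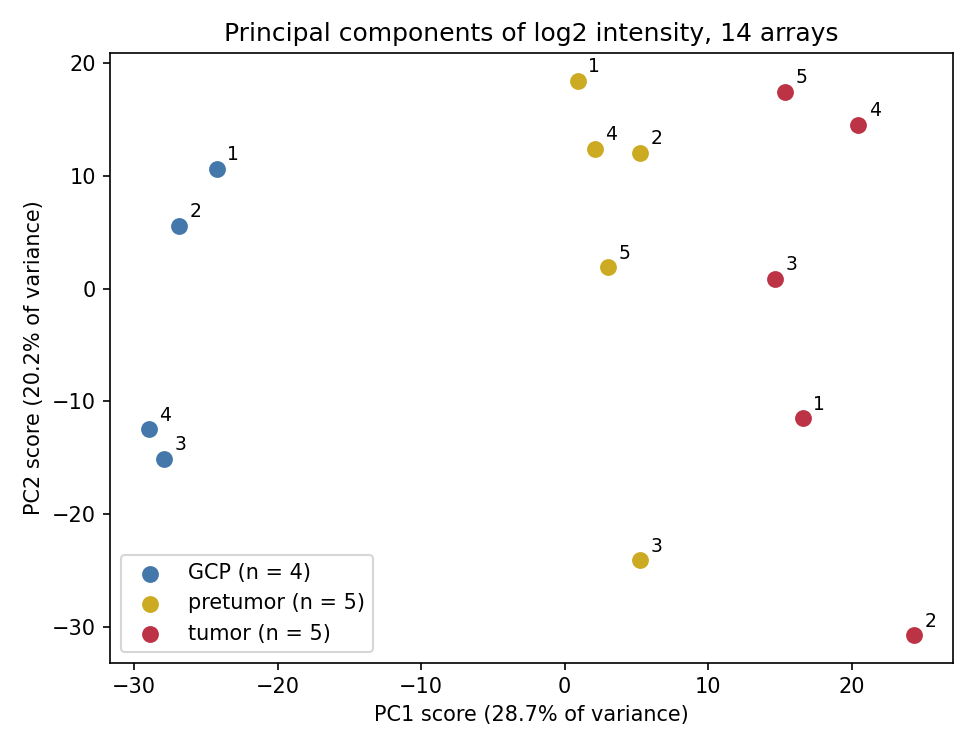
Scores of the 14 arrays on the first component (x axis, 28.7% of the variance) and the second (y axis, 20.2%), coloured by group and numbered by replicate. The groups part along the x axis, with GCP arrays at -24.3 or lower and tumor arrays at 14.7 or higher, while pretumor 3 and tumor 2 lie lowest on the y axis.

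The hedgehog pathway drives the division of granule cell precursors, and Ptch1 is both its receptor and one of its targets. Ptch1 (probe set 104030_at) stood at 7.37 ± 0.12 in GCP, 7.53 ± 0.32 in pretumor and 7.79 ± 0.56 in tumor samples. No difference passed the test (adjusted p = 0.884, 0.501 and 0.745 for pretumor against GCP, tumor against GCP and tumor against pretumor). Its other probe set, 104031_at, stayed in the low band in every group, at 2.03 ± 0.11, 2.00 ± 0.12 and 2.07 ± 0.09. The labels give the same genotype for all mice, so these levels do not check it. The genotype of the cells themselves was not measured. Ccnd2, a cyclin and the hedgehog list member with the highest mean, was at 10.54 ± 0.55, 10.36 ± 0.59 and 10.18 ± 0.88. Of the 13 measured members of the hedgehog list, 6 of them in the low band, limma called 0 in each of the 3 contrasts, and 0 when adjusted over the list alone; at an unadjusted p under 0.05 there were 3, 4 and 2. The list did not pass camera (adjusted p = 0.985, 0.606 and 0.551). Its median, mean and test differed in sign. In pretumor against GCP the median was -0.09, the mean 0.10 and the test down. The mean of the 7 members above the low band was 0.26 higher in pretumor than in GCP samples, at 7.87 ± 0.08 against 7.60 ± 0.08 (exact permutation p = 0.00794). In tumor against GCP it differed by 0.17 (exact permutation p = 0.611), and in tumor against pretumor by -0.09 (p = 0.77). In tumor against GCP the mean was 0.09 and the test up with a median just below 0. In tumor against pretumor the median was 0.09, the mean -0.01 and the test up.

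Preneoplastic cells were compared with granule cell precursors to ask how the 6-week stage differs from the 7-day stage in mice of the same genotype. The immediate early and stress list was higher in the pretumor samples and kept its call with an estimated correlation. The oligodendrocyte list (6 of 13 members up) and the choroid plexus list (1 of 7 up) were higher with the preset correlation and lost their calls with an estimated one. Mal, a myelin membrane protein (99089_at), rose at least 5.94-fold, from 3.38 ± 0.43 to 6.57 ± 0.99, and Car2, a carbonic anhydrase abundant in oligodendrocytes (92642_at), rose 7.16-fold, from 6.49 ± 0.25 to 9.33 ± 0.51. Kl, which encodes klotho, a choroid plexus and kidney protein (100956_at), rose at least 8.47-fold, from 2.04 ± 0.49 to 7.08 ± 1.40. Fabp7, a fatty acid binding protein of radial glia (98967_at), fell by 3.45 on the log2 scale, from 13.24 ± 0.22 to 9.78 ± 0.40. The cholesterol synthesis list was lower under both correlations, and the endothelium, meninges and synapse lists were lower with the preset correlation alone.

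Of 166 calls of genes named by the rule, over the 3 contrasts, 58 ended without at least 1 array. With the compared groups fitted alone 47 ended, and with replicate numbers as a block 45. Arrays that ended a call are given for some genes only. Cldn5 and Mrps22 in pretumor against GCP are among the calls that ended without such arrays being given. Arrays were left out only in contrasts for which the rule named the gene, so Krt10 in pretumor against GCP was not tested in this way. limma called 541 probe sets, 207 higher and 334 lower in pretumor samples, which are 164 and 268 genes, and 338 of them had a group mean above the low band. Among the genes with the largest rises, Krt12, a keratin of the corneal epithelium, rose from 3.14 ± 0.47 to 7.46 ± 0.34 (adjusted p = 3.06e-05), Ptgds, a prostaglandin D2 synthase of meninges, choroid plexus and oligodendrocytes, rose 10.5-fold (adjusted p = 0.00159), and Bag3, a co-chaperone induced by heat, rose 8.97-fold (adjusted p = 0.000722). Gdpd3, a phosphodiesterase, rose at least 3.39-fold (adjusted p = 0.0116), a call that ended with a pseudocount of 16 (adjusted p = 0.118) and with a floor at 16 (adjusted p = 0.0632). Its adjusted p ran from 0.000235 to 0.118 over 28 alternatives. Among the largest falls, Kcnd2, a potassium channel of granule neurons, fell at least 4.81-fold (adjusted p = 3.2e-05), Nid2, a basement membrane protein, at least 3.32-fold (adjusted p = 2.51e-08), and Apbb1ip, an adaptor in integrin activation, at least 5.58-fold (adjusted p = 2.2e-05). Unc5c, a netrin receptor, fell at least 2.90-fold (adjusted p = 1.82e-07), Eomes, a transcription factor of unipolar brush cells, at least 2.62-fold (adjusted p = 0.000872), and Tes, a focal adhesion protein, at least 2.15-fold (adjusted p = 0.000994). Without GCP 4 the count was 331. With the compared groups fitted alone the Gsn call ended, and with replicate numbers as a block those of Fosb, Postn, Mog, Mrps22, Cd180, Tk1, Cldn5 and Rpl13a.

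Of the immediate early and stress list 9 of 28 measured members rose and 0 fell, and 12 rose when adjusted over the list alone. The list joins genes switched on within minutes of a stimulus with heat shock and other stress genes. Its camera adjusted p was 9.52e-10, and adjusted p = 0.0433 with an estimated correlation. Klf4, a transcription factor, rose 4.10-fold from 7.09 ± 0.61 to 9.13 ± 0.71, and Atf3, a transcription factor of the stress response, rose 3.92-fold from 9.82 ± 0.60 to 11.79 ± 0.31. Fosb, a subunit of the AP-1 factor, rose at least 5.36-fold (adjusted p = 0.0428), a call that ended without any 1 of GCP 1 to GCP 4, pretumor 1, 2, 4 and 5 or tumor 5 (adjusted p = 0.0522 to 0.12). The mean of 11 heat shock genes, a list chosen after the comparisons had been seen, was 11.48 ± 0.13 against 10.64 ± 0.13 in GCP (difference 0.85, exact permutation p = 0.00794). Hspa1a, Hspa1b, Hsp90aa1, Dnajb1 and Hspa8 are on both lists, and all but Hspa8 were called higher, so these results overlap. Of the oligodendrocyte list, 6 of 13 measured members rose and 0 fell (9 rose when adjusted over the list alone; camera adjusted p = 7.43e-08). This call was lost with adjusted p = 0.215 with an estimated correlation. Gsn, an actin-severing protein, rose at least 2.65-fold and Mog, a myelin surface protein, at least 2.18-fold, while Mbp, the main myelin basic protein, was at 6.91 ± 0.35 in GCP and 7.16 ± 0.39 in pretumor samples (adjusted p = 0.755). Of the choroid plexus and ependyma list, 1 of 7 members, Kl, rose and 0 fell, with 3 up when adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.278 with an estimated correlation).

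Of the microglia and macrophage list 2 of 28 members rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.353 with an estimated correlation). They were Lyz2, a lysozyme of myeloid cells, 6.82-fold from 4.48 ± 0.93 to 7.25 ± 0.51, and Ctss, a lysosomal protease, 4.56-fold from 7.40 ± 0.75 to 9.59 ± 0.26. Of the MHC and interferon list 4 of 23 members rose and 0 fell, with 5 up when adjusted over the list alone (camera adjusted p = 0.000584, and adjusted p = 0.215 with an estimated correlation). H2-Aa, an MHC class II chain, rose by 0.56 within the low band. Of the G1/S and DNA replication list 3 of 36 members rose and 1 fell, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.00286, and adjusted p = 0.353 with an estimated correlation). Cdc6, a replication licensing factor, rose 2.85-fold from 6.90 ± 0.18 to 8.40 ± 0.35. Tk1, a thymidine kinase, fell 1.78-fold (adjusted p = 0.0185), a call that ended without GCP 1 or GCP 3 (adjusted p = 0.0521 and 0.0631).

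Of the cholesterol synthesis list 0 of 14 members rose and 5 fell, with 10 down when adjusted over the list alone (camera adjusted p = 5.96e-08, and adjusted p = 0.0345 with an estimated correlation). Nsdhl, a sterol dehydrogenase, fell 3.32-fold from 8.40 ± 0.11 to 6.67 ± 0.30, and Hmgcs1, the HMG-CoA synthase of the pathway, fell 2.60-fold from 10.83 ± 0.12 to 9.45 ± 0.37. Of the meninges and extracellular matrix list 1 of 20 members, Ptgds, rose and 6 fell, 1 and 9 when adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.278 with an estimated correlation). Col3a1 and Col4a1, collagen chains of connective tissue and of basement membranes, fell at least 1.56-fold and 3.84-fold. Of the endothelium and pericyte list 0 of 19 members rose and 5 fell, 1 and 9 when adjusted over the list alone (camera adjusted p = 8.48e-05, and adjusted p = 0.215 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, and Tie1, an endothelial receptor, fell by 1.66 and by 1.79 within the low band. Of the synapse and neurofilament list 0 of 29 members rose and 4 fell, 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.215 with an estimated correlation). Nefl, the light neurofilament, fell by 1.53 within the low band. The mean of its 13 members above the low band differed by -0.13 (exact permutation p = 0.27), against -0.23 over all 29. That list's call ended without any 1 of GCP 4, pretumor 1, pretumor 2 or pretumor 3 (adjusted p = 0.0529 to 0.0829). Of the migration and axon guidance list 0 of 33 members rose and 1, Unc5c, fell, also when adjusted over the list alone (camera adjusted p = 0.0423, and adjusted p = 0.278 with an estimated correlation). Its call ended without GCP 2, pretumor 2 or pretumor 3 (adjusted p = 0.0609 to 0.127).

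Tumor cells were compared with granule cell precursors from mice of the same genotype to ask what sets the tumor apart. The immediate early list was higher, and the cholesterol synthesis, endothelium and synapse lists were lower, in tumor samples under both correlations. The astrocyte, postmitotic granule neuron and interneuron lists were lower with the preset correlation alone. Klf4 (99622_at) rose 11.6-fold, from 7.09 ± 0.61 to 10.63 ± 0.39, and Krt10, a keratin of skin epithelium (94321_at), rose 10.7-fold, from 7.64 ± 0.14 to 11.05 ± 0.42. Aqp4, the water channel of astrocytes (102704_at), fell at least 36.5-fold, from 9.19 ± 0.79 to 3.91 ± 1.82, and Fabp7 fell 14.3-fold, to 9.40 ± 0.85. Pax6, a transcription factor of granule cell precursors (92271_at), fell 4.70-fold, from 10.54 ± 0.21 to 8.31 ± 0.33, and Neurod1, which drives granule neurons to mature (92717_at), fell 2.37-fold, from 12.83 ± 0.09 to 11.58 ± 0.46.

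limma called 571 probe sets, 175 higher and 396 lower in tumor samples, which are 140 and 324 genes, and 386 of them had a group mean above the low band. Krt12 rose at least 18.3-fold (adjusted p = 7.94e-06), Fosb at least 19.7-fold (adjusted p = 0.00418), and Lyz2 15.7-fold (adjusted p = 0.000301). Gdpd3 rose at least 9.42-fold (adjusted p = 0.000909) and Foxf2, a forkhead factor of pericytes and mesenchyme, at least 3.09-fold (adjusted p = 1.28e-05). Among the largest falls, Ptprz1, a phosphatase of glial precursors, fell at least 14.4-fold (adjusted p = 0.000143), Mtx2, a mitochondrial import protein, at least 21.0-fold (adjusted p = 0.000319). Gad1, which makes the transmitter GABA, fell at least 5.16-fold (adjusted p = 0.000281), Kcnd2 at least 4.81-fold (adjusted p = 1.21e-05) and Nid2 at least 3.32-fold (adjusted p = 1.26e-08). The globin genes fell, Hbb-b2 from 10.68 ± 0.72 to 4.97 ± 2.80 (adjusted p = 0.0157) and Hba-a1 from 10.57 ± 0.49 to 5.73 ± 2.34 (adjusted p = 0.0182). Both lay in the low band in tumor 3 and tumor 4, so no fold is given. These calls ended without GCP 3 or GCP 4 for Hbb-b2 (adjusted p = 0.0521 at most) and without GCP 2 or GCP 3 for Hba-a1 (adjusted p = 0.058 at most). Without GCP 4 the count was 338, and with the 2 groups fitted alone it was 335, of which 308 were among the 571. Fitted alone, the calls of Ero1b, Hbb-b2, Hba-a1, Ctss, H2-Aa, Col4a1, Smc2, Nes, Pdgfa and Cox6a1 ended, and with replicate numbers as a block those of Smc2, Aldoc, Gdf10 and Pdgfa.

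Of the immediate early and stress list 9 of 28 members rose and 0 fell, with 14 up when adjusted over the list alone (camera adjusted p = 7.12e-11, and adjusted p = 0.0341 with an estimated correlation). The mean of the 11 heat shock genes was 11.23 ± 0.21 against 10.64 ± 0.13 (difference 0.60, exact permutation p = 0.00794). Myc, a growth-promoting transcription factor on the immediate early and stress list, rose at least 1.15-fold from 2.05 ± 0.06 to 4.20 ± 0.70 (adjusted p = 0.00171). That call ended with a floor at 16 (adjusted p = 0.269, with a range of 0.000355 to 0.269 over 28 alternatives). Of the microglia and macrophage list 2 of 28 members rose and 0 fell, with 3 up when adjusted over the list alone (camera adjusted p = 0.00118, and adjusted p = 0.276 with an estimated correlation). Of the G1/S and DNA replication list 4 of 36 members rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.276 with an estimated correlation). Cdc6 rose 2.08-fold to 7.95 ± 0.19. Of the MHC and interferon list 2 of 23 members rose and 0 fell, with 4 up when adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.276 with an estimated correlation). Its call ended without tumor 2 or tumor 3 (adjusted p = 0.0566 for each). In the low band lay 18 of its members, among them the 2 called, H2-Aa and H2-Eb1. The H2-Aa call ended without any 1 of 11 arrays, and that of H2-Eb1 without any 1 of 8. The mean of the 5 members above the low band differed by 0.39 (exact permutation p = 0.111). Of the ribosomal protein list 1 of 17 members, Rpl13a, rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0404, and adjusted p = 0.283 with an estimated correlation). Its call ended without GCP 1, GCP 2, tumor 4 or tumor 5 (adjusted p = 0.0717 to 0.156).

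Of the cholesterol synthesis list 0 of 14 members rose and 6 fell, with 12 down when adjusted over the list alone (camera adjusted p = 2.8e-11, and adjusted p = 0.00841 with an estimated correlation). Hmgcs1 fell 3.48-fold to 9.03 ± 0.35, Nsdhl 3.35-fold to 6.66 ± 0.28, and Idi1, an isomerase of the same pathway, 2.56-fold to 8.12 ± 0.45. Of the endothelium and pericyte list 0 of 19 members rose and 8 fell, with 13 down when adjusted over the list alone (camera adjusted p = 2.8e-11, and adjusted p = 0.0341 with an estimated correlation). Cldn5, a tight junction protein of brain vessels, fell at least 3.48-fold from 5.80 ± 0.27 to 2.93 ± 0.74. Of the astrocyte and Bergmann glia list 0 of 17 members rose and 8 fell, with 9 down when adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.0901 with an estimated correlation). Among them Gdf10, a growth factor of Bergmann glia, fell 12.4-fold from 8.10 ± 0.50 to 4.48 ± 1.46. Of the meninges and extracellular matrix list 0 of 20 members rose and 6 fell, with 8 down when adjusted over the list alone (camera adjusted p = 2.61e-05, and adjusted p = 0.276 with an estimated correlation).

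Of the synapse and neurofilament list 0 of 29 members rose and 7 fell, with 8 down when adjusted over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.0459 with an estimated correlation). Of the postmitotic granule neuron list 0 of 16 members rose and 3 fell, with 5 down when adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.117 with an estimated correlation). The 3 that fell were Kcnd2, Neurod1 and Cbln1, a synaptic organiser of granule neurons, the last by 0.91 within the low band. Of the inhibitory interneuron list 0 of 10 members rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.269 with an estimated correlation). Its call ended without tumor 2 or tumor 3 (adjusted p = 0.0566 and 0.0602). Of its 10 members 8 lay in the low band. Of the glycolysis list 0 of 17 members rose and 4 fell, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.269 with an estimated correlation). Tpi1, the triose phosphate isomerase, fell 3.60-fold from 11.50 ± 0.06 to 9.65 ± 0.60. Of the oxidative phosphorylation list 0 of 31 members rose and 1 fell, with 2 down when adjusted over the list alone (camera adjusted p = 0.0089, and adjusted p = 0.276 with an estimated correlation). The member that fell, Cox6a1, a cytochrome oxidase subunit, did so by 0.38, a call that ended without GCP 2, GCP 3, GCP 4, tumor 1 or tumor 4 (adjusted p = 0.0582 to 0.0899).

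**Figure D2:**
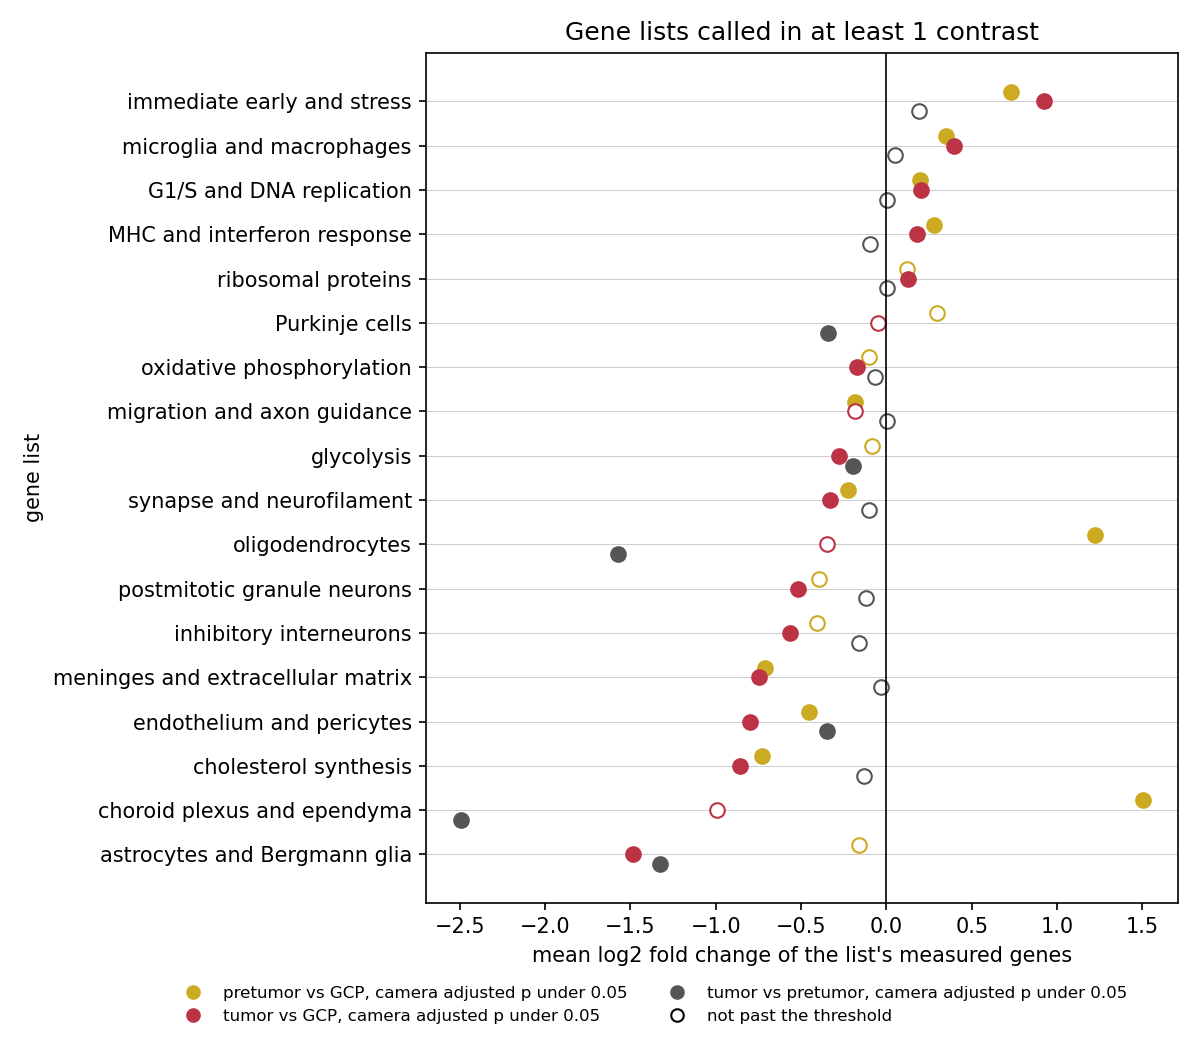
Mean log2 fold change (x axis) of the measured genes of each list called in at least 1 contrast (y axis), coloured by contrast, with filled points for a camera adjusted p under 0.05 and open points otherwise. Cholesterol synthesis lies below 0 in both contrasts with GCP (-0.73 and -0.86), while oligodendrocytes lie at 1.22 for pretumor against GCP and at -1.57 for tumor against pretumor.

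Tumor cells were compared with preneoplastic cells to ask what differs between the last 2 stages. The astrocyte, oligodendrocyte and choroid plexus lists were lower in tumor samples under both correlations. Ptprz1 (92379_f_at) fell at least 9.14-fold, from 7.19 ± 0.10 to 3.16 ± 1.20, Car2 fell 14.5-fold to 5.47 ± 1.01, and Ptgds (92545_f_at) fell 19.1-fold, from 8.82 ± 0.28 to 4.56 ± 0.85. Krt10 rose 2.53-fold, from 9.71 ± 0.36 to 11.05 ± 0.42, and Snx10, a protein of endosome sorting (94556_at), rose 2.24-fold, from 5.02 ± 0.10 to 6.18 ± 0.24. Slc8a1, a sodium and calcium exchanger (99524_at), rose 2.10-fold, from 4.15 ± 0.18 to 5.22 ± 0.17.

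limma called 124 probe sets, 26 higher and 98 lower in tumor samples, which are 11 and 79 genes, and 79 of them had a group mean above the low band. Calml4, a calmodulin-like protein, fell at least 24.5-fold (adjusted p = 0.000523), Smpdl3a, a phosphodiesterase, 10.9-fold (adjusted p = 0.00408). Mal fell at least 5.94-fold (adjusted p = 0.00366), Kl at least 8.47-fold (adjusted p = 0.00453) and Gsn at least 2.65-fold (adjusted p = 0.00535). Myc rose at least 1.15-fold (adjusted p = 0.0129), and Cdk8, a kinase of the Mediator complex, rose 1.49-fold (adjusted p = 0.0237), a call that ended without any 1 of pretumor 1, 2, 4 and 5 or tumor 2 (adjusted p = 0.0568 to 0.0645). With both groups fitted alone the count was 50, of which 47 were among the 124, and the calls of Krt10 and Myc ended (adjusted p = 0.0662 and 0.0823), as did those of Mrps22, Selenof, Evi2a, Ndrg1, Cd180, Sox2 and Mt2. The Myc call also ended with replicate numbers as a block (adjusted p = 0.0796), like those of Mrps22, Mog, Evi2a, Cd180 and Sox2, and with a floor at 16 (adjusted p = 0.416). Over 28 alternatives the adjusted p ran from 0.00275 to 0.0662 for Krt10 and from 0.00376 to 0.416 for Myc. The count was 72 without pretumor 1, 70 without pretumor 2 and 70 without tumor 4.

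Of the astrocyte and Bergmann glia list 0 of 17 members rose and 7 fell, with 12 down when adjusted over the list alone (camera adjusted p = 1.27e-17, and adjusted p = 0.0406 with an estimated correlation). Gpr37l1, an orphan receptor of astrocytes, fell 5.06-fold from 7.05 ± 0.76 to 4.71 ± 0.34. Of the oligodendrocyte list 0 of 13 members rose and 6 fell, 1 and 10 when adjusted over the list alone (camera adjusted p = 1.16e-15, and adjusted p = 0.0421 with an estimated correlation), Mbp among them, 3.12-fold to 5.52 ± 0.37. Of the choroid plexus and ependyma list 0 of 7 members rose and 2 fell, with 5 down when adjusted over the list alone (camera adjusted p = 3.37e-09, and adjusted p = 0.0447 with an estimated correlation). Of the endothelium and pericyte list limma called 0 of 19 members, 6 had an unadjusted p under 0.05, and 6 were down when adjusted over the list alone (camera adjusted p = 0.000433, and adjusted p = 0.346 with an estimated correlation). Of the Purkinje cell list 0 of 13 members rose and 1 fell, with 3 down when adjusted over the list alone (camera adjusted p = 0.0285, and adjusted p = 0.346 with an estimated correlation). Its call ended without pretumor 1, pretumor 3, tumor 1 or tumor 4 (adjusted p = 0.0614 to 0.0828). Of the glycolysis list 0 of 17 members rose and 3 fell, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.0285, and adjusted p = 0.387 with an estimated correlation). Its call ended without pretumor 1 or tumor 4 (adjusted p = 0.0566 and 0.0897). The mean of the 10 glycolysis members above the low band differed by 0.02 (exact permutation p = 0.841) against -0.20 over all 17, so the fall of the mean lay in members of the low band. Aldoc, the aldolase of astrocytes, which is on the glycolysis and the astrocyte lists, fell by 1.92 within the low band. The immediate early list did not pass here (adjusted p = 0.472), with 1 of 28 members, Myc, up and 1, Mt2, a metallothionein, down 2.40-fold from 7.13 ± 0.42 to 5.87 ± 0.36.

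The preneoplastic stage was then set against both other stages at once. In 41 probe sets pretumor samples lay apart from both, 33 higher and 8 lower, which are 27 and 4 genes, and 21 had a group mean above the low band. Higher in pretumor samples were Kl, Ptgds, Mal, Car2, Gsn and Mog, and Ndrg1, a protein of myelinating cells (96596_at), at 7.50 ± 0.52 against 5.60 ± 0.12 in GCP and 5.36 ± 0.71 in tumor samples. Of these, Mal, Car2, Gsn and Mog are members of the oligodendrocyte list. Slc8a1 was lower in pretumor samples, at 4.15 ± 0.18 against 5.77 ± 0.02 and 5.22 ± 0.17. Evi2a was also higher, and Mrps22, Selenof and Cd180 were also lower. In tumor against pretumor, leaving out any 1 of 10 arrays ended the Evi2a call, 1 of 7 the Mrps22 call, and 1 of 12 the Selenof and Cd180 calls (adjusted p = 0.114 at most). Independent calls of the same sizes would overlap in 1.63 probe sets higher and 0.699 lower, which compares with 33 and 8 observed. With the pretumor arrays split so that each contrast used its own, 20 splits gave 7 to 23 probe sets (median 12.5). Across genes pretumor minus GCP and tumor minus pretumor correlated at -0.22, closer to 0 than the -0.47 of 20 simulations of unchanged groups. In the splits pretumor minus GCP and pretumor minus tumor correlated at -0.01 to 0.18, where a value above 0 means lying apart. The count was 24 without GCP 1, 26 without GCP 2, 25 without GCP 3, 22 without GCP 4, 26 without pretumor 1, 26 without pretumor 2 and 25 without tumor 4, and 16 when each pair of groups was fitted alone.

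Pretumor and tumor samples were also compared in how they differ from GCP. In 302 probe sets both differed from GCP in the same direction, 88 higher and 214 lower, which are 68 and 179 genes, and 197 had a group mean above the low band. Higher in both were Krt12, Gdpd3, Klf4, Lyz2, Bag3 and Krt10, the last at 7.64 ± 0.14, 9.71 ± 0.36 and 11.05 ± 0.42 in GCP, pretumor and tumor samples. Lower in both were Fabp7, Kcnd2, Nid2, Unc5c, Eomes, Apbb1ip, Pax6, Neurod1, Nsdhl and Hmgcs1. Both contrasts use the same 4 GCP arrays. Independent calls would overlap in 2.92 probe sets higher and 10.6 lower, which compares with 88 and 214 observed. With the GCP arrays split into pairs, 1 pair for each contrast, 6 splits gave 91 to 120 shared probe sets (median 97). Across genes, which are not independent replicates, the fold changes correlated at 0.705 against 0.558 in 20 simulations of unchanged groups, and their covariance was 0.102 against 0.0166, a difference of 0.0856. The share of probe sets with changes of the same sign was 65.2%, below the 66.7% of the simulations (66.0% to 67.7%). Simulated values were independent, while the real arrays share an axis of deviations, so the simulated range may be too narrow. Without GCP 4 the count was 182, and with the 2 groups of each contrast fitted alone it was 192.

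**Figure D3:**
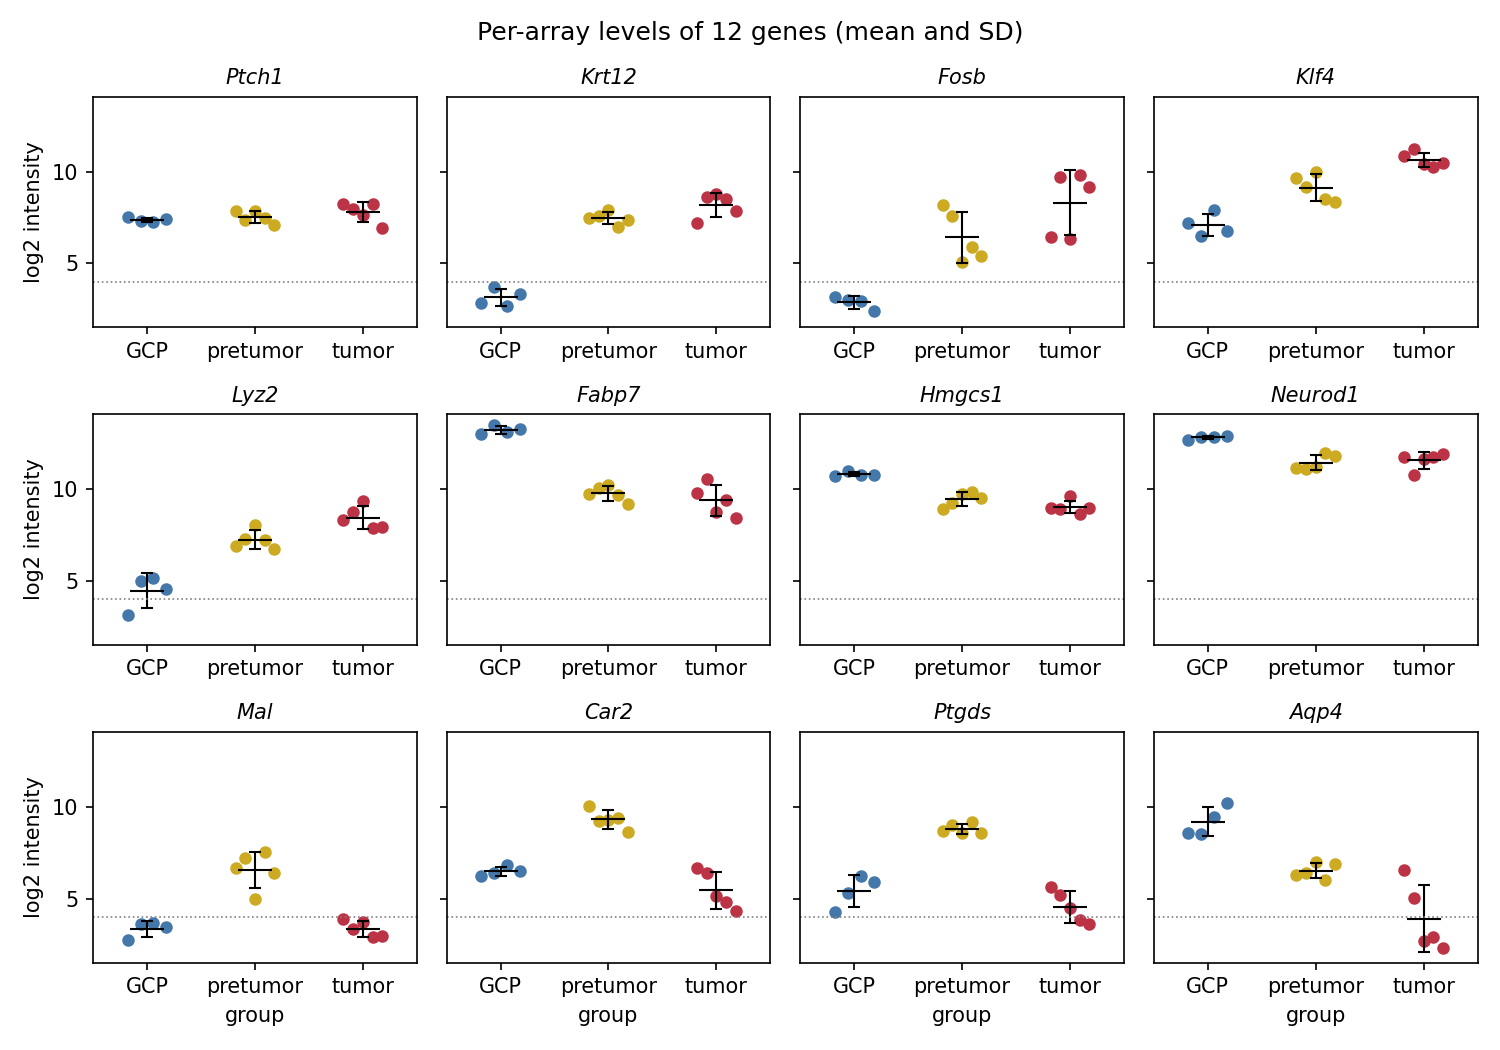
Log2 intensity (y axis) of 12 genes on each array, by group (x axis), with the mean and SD of GCP (n = 4), pretumor (n = 5) and tumor samples (n = 5) and a dotted line at an intensity of 16. Ptch1 overlaps between groups, Klf4 and Lyz2 are lowest in GCP, Fabp7, Hmgcs1 and Neurod1 are highest in GCP, and Mal, Car2 and Ptgds are highest in pretumor samples.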

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

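Single arrays were screened by a rule fixed before the data were examined, and the tests of the control probe sets were chosen after seeing the data. The screen covered 191 groups of values, each 1 gene or list mean in 1 group of samples, and 6 held an array far from the rest of its group. Chance alone marks about 1 in 20 such groups.

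Krt10 stood at 7.85 in GCP 3 and between 7.55 and 7.59 in the other GCP samples. Mtx2 stood at 4.92 in pretumor 3 and between 6.55 and 7.17 in the other pretumor samples. Slc8a1 stood at 3.83 in pretumor 1 and between 4.19 and 4.26 in the other pretumor samples. The mean of the Purkinje cell list was 2.44 in tumor 3 and between 2.16 and 2.24 in the other tumor samples, and the mean of the neural stem and progenitor list was 5.19 in tumor 3 and between 4.98 and 5.03 in the others. The mean of the Wnt and BMP list was 2.69 in tumor 2 and between 2.86 and 2.92 in the other tumor samples.

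A control probe set for the murine B2 repeat, which the comparisons leave out, was 0.34 higher on the log2 scale in pretumor than in GCP samples, at 13.07 ± 0.09 against 12.72 ± 0.04 (exact permutation p = 0.00794, adjusted p = 0.0397 over 5 tests). No explanation of this difference was tested.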

How the results depend on the processing

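The floor at 16, the covariate for the residual axis, the arrays on either side of that axis, the plain-suffix probe sets and the removal of pretumor 3, tumor 2 and tumor 3 together were chosen after seeing the data. The other alternatives were fixed before. The residual axis is the first component of the deviations from the group means. Counts are given in the order pretumor against GCP, tumor against GCP, tumor against pretumor, pretumor apart from both and shared change, which were 541, 571, 124, 41 and 302 as reported, with 31 lists called.

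Every count stayed within 1.5 times its reported value with quantile normalization, median-centred arrays, a floor at the 25th percentile, a pseudocount of 16, dim probe sets left out, trend and robust moderation, the mean of a gene's probe sets, plain-suffix probe sets, and pretumor 3, tumor 2 and tumor 3 left out together.

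With 2 groups compared alone, tumor against GCP gave 335, tumor against pretumor 50, apart from both 16 and shared change 192. With replicate numbers as a block, tumor against pretumor gave 76 and apart from both 27. Deviations of arrays with the same number correlated between -0.32 and 0.51 (median -0.04 over 13 pairs). Those of arrays with other numbers ran from -0.52 to 0.48 (median 0.04). These values show no clear pairing by number, but the residual axis enters them too, so they cannot exclude it. Array weights gave 1508, 997, 393, 151 and 619. The cause was not tested for these settings.

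A floor at 16 left 24 probe sets apart from both and 15 lists, and the change of the glycolysis list in tumor against pretumor and of Aldoc in tumor against GCP became 0, since such values lie at the floor. Among the lists still tested with that floor 14 list calls were lost, so list calls given above may rest on members in the low band. The axis as a covariate gave 976, 933, 253, 91 and 498, since it removes spread within groups by construction. Arrays above 0 on the axis gave 9, 38, 0, 0 and 6, and arrays below 0 gave 158, 158, 58, 20 and 82, with fewer samples in each fit. Above 0 the median change of the mitosis list in tumor against GCP went from -0.02 to 0.15 and the list passed (adjusted p = 0.038), and the cause was not tested.

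A minimum of 2-fold left 189, 227 and 62 probe sets in the 3 contrasts, and an adjusted p under 0.01 left 13 apart from both and 130 shared, each a stricter threshold. An estimated correlation in camera left 9 lists, 2 up and 7 down, and fry called 35.

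With 1 array left out at a time the counts ran from 331 to 624, from 338 to 712, from 70 to 148, from 22 to 59 and from 182 to 356, and lists from 28 to 37. Of 166 gene calls 58 ended without at least 1 array, and of 31 list calls 7. For probe sets in the low band changes are given without a fold.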

Other observations

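Genes of neural stem cells, growth factors and red blood cells differed singly while their lists did not pass. Nes, an intermediate filament of neural progenitors, rose 4.26-fold in tumor against GCP samples, from 6.17 ± 0.27 to 8.26 ± 0.92 (adjusted p = 0.015), a call that ended without GCP 4 (adjusted p = 0.0549). Sox2, a transcription factor of stem cells and glia, fell 7.19-fold, from 9.23 ± 0.15 to 6.39 ± 1.03 (adjusted p = 0.00351). Pdgfa, a growth factor for glial progenitors, rose 3.28-fold in tumor samples, a call that ended without GCP 1, GCP 2 or GCP 4 (adjusted p = 0.059 to 0.062). Smc2, a condensin subunit of mitotic chromosomes, rose 1.91-fold (adjusted p = 0.0146). Zic1, a transcription factor of granule cell precursors, was at 12.74 ± 0.11, 12.59 ± 0.16 and 12.64 ± 0.21 in GCP, pretumor and tumor samples and was not called. Postn, a matrix protein, fell at least 1.97-fold in pretumor samples (adjusted p = 0.0372), a call that ended without any 1 of the GCP or pretumor arrays (adjusted p = 0.0617 to 0.107). Ero1b, an oxidase of the endoplasmic reticulum, rose at least 10.6-fold in tumor samples (adjusted p = 0.0297), a call that ended without any GCP array or tumor 2 (adjusted p = 0.0565 to 0.0846).

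In pretumor against GCP these lists did not pass camera. Granule cell precursor identity had 0 members up and 1 down (adjusted p = 0.144), mitosis 0 and 3 (0.538), cell cycle inhibitors 1 and 0 (0.108), apoptosis regulators 1 and 1 (0.998), postmitotic granule neurons 0 and 3 (0.229), and Purkinje cells 1 and 1 (0.0827). Inhibitory interneurons had 0 up and 3 down (0.0896), astrocytes and Bergmann glia 2 and 1 (0.291), neural stem and progenitor genes 0 and 2 (0.48), growth factor signalling 0 and 1 (0.936), glycolysis 1 and 2 (0.998), oxidative phosphorylation 1 and 0 (0.229), ribosomal proteins 1 and 0 (0.0742) and chromatin 0 and 1 (0.585). limma called 0 oligodendrocyte progenitor (0.144), lymphocyte (0.665), red blood cell (0.538) and Wnt and BMP genes (0.995), with 1, 1, 0 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, up and down counts differed for mitosis (1 and 3), apoptosis (2 and 2), postmitotic granule neurons (0 and 4), Purkinje cells (2 and 1), interneurons (1 and 3), astrocytes (5 and 3), oligodendrocyte progenitors (0 and 1), neural stem genes (2 and 2), growth factors (2 and 2) and glycolysis (2 and 3). Median, mean and test differed in sign for apoptosis (-0.01, 0.04, up), astrocytes (0.11, -0.16, up) and Wnt and BMP (-0.02, 0.02, up), and for lymphocytes and growth factors (median just under 0, mean 0.01 and 0.03, up) and glycolysis (median just over 0, mean -0.08, down). The Purkinje list passed without GCP 4 or pretumor 2 (adjusted p = 0.0356 to 0.0479), interneurons (0.0444), oligodendrocyte progenitors (0.0462) and oxidative phosphorylation (0.0436) without GCP 1, and ribosomal proteins without GCP 3, GCP 4 or pretumor 4 (0.0361 to 0.0393).

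In tumor against GCP the lists that did not pass were granule cell precursor identity with 0 up and 1 down (adjusted p = 0.0581), mitosis 1 and 0 (0.948), apoptosis 0 and 1 (0.179), migration 0 and 2 (0.0954), Purkinje cells 0 and 1 (0.801), oligodendrocytes 0 and 1 (0.118), their progenitors 0 and 1 (0.0533), red blood cells 0 and 2 (0.0997), choroid plexus 0 and 1 (0.0533), neural stem genes 2 and 2 (0.928), growth factors 2 and 2 (0.948) and chromatin 0 and 1 (0.309). limma called 0 cell cycle inhibitors (0.0521), lymphocyte (0.5) and Wnt and BMP genes (0.606), with 6, 1 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, counts differed for inhibitors (1 and 1), apoptosis (2 and 3), migration (0 and 4), red blood cells (0 and 3) and growth factors (4 and 4). Signs differed for mitosis (median -0.02, mean 0.04, test down) and growth factors (median and mean -0.01, test up). Several lists passed without single arrays: inhibitors without GCP 4, pretumor 1 or 2, or tumor 4 or 5 (0.0233 to 0.0488), and choroid plexus without GCP 1, pretumor 1 or 4, or tumor 1 or 3 (0.0358 to 0.0482). Precursor identity (0.00856 to 0.0497) and oligodendrocyte progenitors (0.018 to 0.0497) passed without GCP 1 or 3, pretumor 1 or 2, or tumor 1, and oligodendrocytes without GCP 1 (0.0326).

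In tumor against pretumor limma called 1 meninges gene down (adjusted p = 0.505 for the list) and 1 neural stem gene down (0.225). Of the lists named next it called 0 members, with these counts at an unadjusted p under 0.05: granule cell precursor identity 1 (0.654), G1/S 3 (0.942), mitosis 4 (0.449), inhibitors 3 (0.803), apoptosis 3 (0.225), migration 4 (0.727), postmitotic granule neurons 5 (0.212) and synapse 6 (0.225). For the rest they were interneurons 3 (0.551), oligodendrocyte progenitors 1 (0.622), microglia 3 (0.648), lymphocytes 1 (0.803), MHC 3 (0.207), red blood cells 3 (0.225), growth factors 8 (0.803), Wnt and BMP 1 (0.647), oxidative phosphorylation 2 (0.0845), ribosomal proteins 1 (0.803), cholesterol synthesis 1 (0.0845) and chromatin 0 (0.712). Adjusted over the list alone, up and down counts were 1 and 1 for inhibitors, 0 and 2 for postmitotic granule neurons, interneurons, red blood cells and meninges, 0 and 1 for oligodendrocyte progenitors, 2 and 2 for growth factors, and 3 and 2 for the immediate early list. Median, mean and test differed in sign for G1/S (-0.01, 0.01, up), synapse (0.01, -0.10, down), interneurons (0.02, -0.16, down), meninges (0.26, -0.03, up) and growth factors (0.02, -0.04, up). MHC passed without tumor 2 (0.0434), mitosis without tumor 3 (0.0203), oxidative phosphorylation without pretumor 4 or tumor 2 (0.00826 to 0.018), and cholesterol synthesis without pretumor 1 or 2 or tumor 3 or 5 (0.0255 to 0.0495).

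For 3 patterns explanations were tested. The tests of a lower granule-lineage share and of the loss of 5' signal were chosen only after the result was seen. Of the oligodendrocyte and choroid plexus lists, 6 of 13 and 1 of 7 members were called higher in pretumor than in GCP samples, list calls that were lost with an estimated correlation (adjusted p = 0.215 and 0.278), and 6 and 2 were called lower in tumor than in pretumor samples. A lower share of granule-lineage cells, with other cell types in fixed proportions, would raise the markers of those types alike. Against GCP the endothelium mean was -0.46 and the meninges mean -0.71 in pretumor samples (exact permutation p = 0.00794 for each), with oligodendrocytes at 1.22 (p = 0.0159). Interneurons (-0.41), oligodendrocyte progenitors (-0.36), red blood cells (-0.33) and astrocytes (-0.16) were also lower. Higher microglia (0.35), Purkinje (0.30) and choroid plexus means (1.51), and lower precursor identity (-0.28) and postmitotic granule neuron means (-0.40), go with a lower share. Proportions at 7 days and 6 weeks were not measured, so against GCP it stays open. Against tumor, the oligodendrocyte minus microglia mean was 2.49 higher in pretumor samples (exact permutation p = 0.00794). This used the 7 and 6 members above the low band, which Mal, Gsn and Mog join only through their pretumor level. Over all members, tumor minus pretumor means were -1.57 for oligodendrocytes and 0.05 for microglia. Fixed proportions would move both alike, but proportions in tumors were not measured, so a lower share stays open against tumor too. Tumor minus pretumor means of astrocytes (-1.32), choroid plexus (-2.49), red blood cells (-1.01), endothelium (-0.35) and Purkinje cells (-0.34) go with it. Mature oligodendrocytes carried into the suspensions may contribute: 18 further oligodendrocyte genes had a median change of 0.12 against GCP, at percentile 99.95 of random lists, and of -0.06 in tumor against pretumor, at percentile 0.78, which is what this explanation predicted. The median against GCP lay between Itgb4 (0.09) and Pmp22 (0.15), both in the low band, so that percentile rests on small changes there. Against GCP limma called only Nkx6-2 of these genes (adjusted p = 0.00309), also in the low band. In tumor against pretumor it called Nkx6-2 and Septin4, the latter above the low band (-1.56, adjusted p = 0.000474). Mbp fell 3.12-fold in tumor against pretumor but did not pass in pretumor against GCP, which leaves carried-over oligodendrocytes open. Age and stage stay open and untested.

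An axis of deviations from the group means crossed all groups. The Gapdh 3' to 5' ratio followed the axis with r = -0.72 (permutation p = 0.00063, adjusted p = 0.00378, rho = -0.63 with p = 0.00699; -0.63 without tumor 2 and pretumor 3), but the actin 3' to 5' ratio ran the other way with r = 0.46 (permutation p = 0.167, adjusted p = 0.242, rho = 0.51 with p = 0.133; 0.37 without them), which leaves a loss of 5' signal open. The mitosis list gave r = 0.18 (permutation p = 0.627, adjusted p = 0.627, rho = 0.16 with p = 0.65; -0.17 without the same arrays), which met the limit set beforehand for excluding the share of cycling cells, absolute r under 0.3. With 14 arrays that limit was wrong, since the interval of -0.44 to 0.68 reaches past it, and this was judged after the value was seen, so the explanation stays open. The immediate early list gave r = -0.43 (permutation p = 0.124, adjusted p = 0.242, rho = -0.43 with p = 0.112; -0.55 without them), which leaves stress during isolation open. No other biological explanation of the axis was tested.

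Immediate early genes were higher in pretumor and tumor than in GCP samples. Here they are 15 genes above the low band, a list kept apart from the immediate early and stress list. Within groups, their mean followed the heat shock mean with r = -0.40 (permutation p = 0.184, adjusted p = 0.242, rho = -0.31 with p = 0.303; -0.24 without tumor 5 and tumor 4) and the microglia mean with r = -0.39 (p = 0.202, adjusted p = 0.242, rho = -0.37 with p = 0.225; -0.17 without tumor 3 and GCP 1), over 6 relations in all. Both values met the limit set beforehand for excluding these explanations, r under 0.3. That limit was wrong, since handling can differ between groups and be even within them. The heat shock (0.85 and 0.60) and microglia means (0.98 and 1.06) were themselves higher than in GCP. This microglia mean, also used in the correlation, is over the 6 members above the low band. Over all 28 members the differences were 0.35 and 0.40. Heat shock during isolation, more microglia, and age or stage stay open.

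For 5 of the 6 counts the real grouping gave more calls than any other split tried into groups of the same sizes. The other splits mix stages, which widens the spread within groups and lowers counts of probe sets. They show that counts as large are rare under regrouping. They exclude neither chance nor a batch that runs along with the groups. The highest count of 100 splits besides the real one was 113 against 541 for pretumor against GCP, 36 against 571 for tumor against GCP, 5 against 41 for pretumor apart from both, 1 against 302 for shared change and 27 against 31 for lists, so that only 1 split, the real one, reached each of these. The median of the other splits was 13 lists and 0 for each other count, so the list test with the preset correlation calls many lists in other groupings too. For tumor against pretumor 2 of 100 splits reached 124, the real one included, which is a small share, but the other gave 811, setting pretumor 1, 2 and 4 with tumor 4 and 5, which lie below 0 on the axis of deviations. That points to a structure of the samples other than the groups.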
